A study of Arabidopsis thaliana with 13 samples.

How the data were processed

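RNA of whole Col-0 seedlings was measured on Affymetrix ATH1 arrays, which read each transcript with a set of short probes. Per the labels, plants were grown in a growth room at 22 C with a 12 h photoperiod on MS agar with 3% sucrose, and 13 samples were taken between hours 26 and 74. Each time point is a group of its own with 1 array.

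The deposited values are intensities on a linear scale, 1 per probe set, and MAS5 is named in the submitters' processing notes, with no version given in the sources used here. The values fit a scaling of every array to 1 target, since the mean of each array without its top and bottom 2% was 100.01. Such scaling hides any change in total RNA per cell and leaves dim probe sets noisy. Detection calls were not used here.

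Log2 of the 22746 non-control probe sets was analysed, and 13647 whose mean lay above the 40th percentile were tested. The linear model held time, and the cosine and sine of a 24 h period. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and Benjamini-Hochberg adjusted p-values under 0.05 were called. Rhythm was tested by the moderated F of cosine and sine, and drift by the time coefficient. An amplitude is the height of the fitted curve above its mean on the log2 scale, and its change from trough to peak is 2 amplitudes. The cycles were compared on the 12 arrays of hours 26 to 70 by the interaction of cosine and sine with the later cycle. The best period was the one with the lowest residual sum of squares between 20 and 30 h.

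The platform annotation used here gave 1 gene to 13513 of the non-control probe sets, several to 503 and none to 8730. Symbols were updated through the gene table of the TAIR10.1 assembly, which matched 13436 of the 13513. Probe sets without a single gene were tested but are not named, and no coordinates are given because the build behind the array is not given in the sources used here. The 20 gene lists held 292 loci, of which 39 had a named probe set and 35 were tested, so most members, among them most core clock genes, were not analysed here by name. Each locus was represented by its brightest probe set. RVE6, SAND, TIP41, COR28 and CDF5 are named by the loci fixed in the lists, where the gene table gives only the locus as symbol. The lists for photoreceptors, photoperiodic flowering, nitrogen assimilation, reactive oxygen scavenging, cell cycle, touch and wounding, pathogenesis and heat shock had 0 tested members.

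Lists with at least 3 tested members were compared with the other tested genes by Fisher's exact test, two-sided, and their mean standardised profiles were tested against 100000 random orders of the arrays. Drift of lists was also tested with camera. Tests, lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named every clock gene, up to 4 called and 2 uncalled members of each other list, the 3 largest amplitudes in each of 4 parts of the day, the 5 steepest rises and falls, and the 5 smallest p-values of the cycle comparison, and some of these are left out of the text. Alternatives changed the scaling, the offset, the filter, the variance model, the terms and period of the curve, and the arrays included.

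The fits were tested on simulated data with 13647 probe sets. Of rhythms with an amplitude of 0.25, 0.5 and 1, 31.3%, 77.6% and 100% were recovered, and 4.79% of the rhythmic calls were false. Of slopes of those sizes, 17.9%, 88.1% and 98.5% were recovered, with 4.23% of calls false. Each size was seeded in 66 or 67 of the 13647 probe sets. Far fewer were thus rhythmic than the 2504 called in the real data, which makes the adjusted p stricter. The simulated noise was also independent between probe sets and of equal size on every array, so these rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9.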

Results

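Transcript levels were followed in whole seedlings of the Arabidopsis thaliana accession Col-0 through a single time course on Affymetrix ATH1 arrays. The course held 13 arrays, taken every 4 h from hour 26 to hour 74, with 1 array per time point. The series title places the work in the study of circadian expression and of models of the plant clock. The labels do not say what hour 0 was or whether the lights kept cycling during sampling, so peak times are given as hours of the course modulo 24. There were no separate replicates of a time point, so p-values measure the scatter of the arrays round a fitted curve, and the number of arrays limits the precision. The trimmed mean signal was 100.01 on every array, and the median signal of the non-control probe sets lay between 46.8 and 50.9.

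Arrays taken 24 h apart were on average the most alike. After each probe set was centred on its mean, the correlation between arrays across the 13647 probe sets tested averaged 0.38 for the 7 pairs of arrays 24 h apart, with a range of 0.23 to 0.58. It was 0.18 for the 1 pair 48 h apart, hours 26 and 74. It averaged -0.42 for the 10 pairs 12 h apart, with a range of -0.53 to -0.26. Pairs of neighbouring arrays, 4 h apart, averaged 0.19. These are correlations across genes, which are not independent replicates. The leading pair of principal components held 29.3% and 21.0% of the variance.

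**Figure D1:**
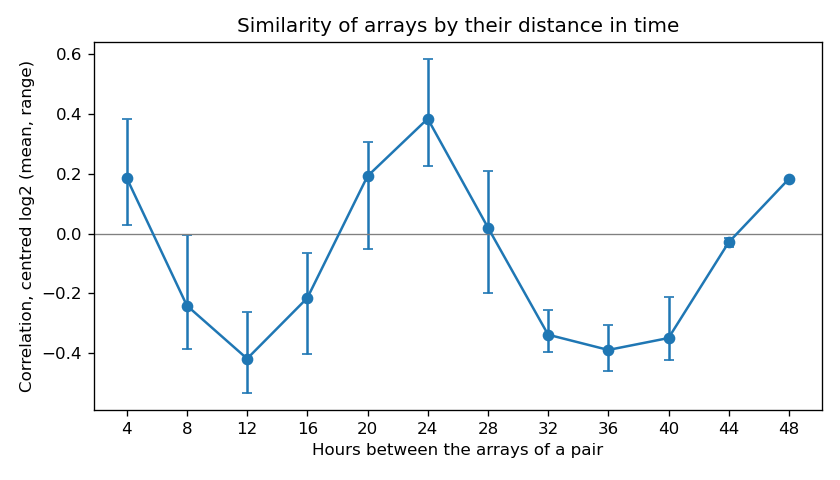
Mean correlation of gene-centred log2 signals between arrays (y axis) against the hours between the arrays of a pair (x axis), with bars from the lowest to the highest pair. The mean is 0.38 at 24 h, -0.42 at 12 h and 0.18 for the 1 pair at 48 h.

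The first comparison asked which transcripts followed a 24 h rhythm. The largest swing among probe sets with a single named gene belonged to AT4G14090, known as an anthocyanin glucosyltransferase, with an amplitude of 3.47 ± 0.33 (SE, log2 scale) and a peak at hour 21.7. DFR, the dihydroflavonol reductase of anthocyanin synthesis, peaked at hour 22.7 with a 20.2-fold change from trough to peak, and AT2G15020 peaked at hour 22.0 with a 22.6-fold change. In the early hours of the day, AT5G03350 peaked at hour 1.96 (12.5-fold) and AT5G62280 at hour 5.68 (11.0-fold). AT2G03310 followed at hour 9.33 (12.0-fold) and AT3G62550 at hour 10.1 (10.2-fold), then AT1G07050 at hour 11.9 (9.50-fold), AT4G32340 at hour 12.1 (10.4-fold) and AT4G34950 at hour 13.2 (8.10-fold). In limma's moderated F test, 2504 of the 13647 probe sets (18.3%) were rhythmic at an adjusted p under 0.05. The lowest signals of AT4G14090 (2.15), AT2G15020 (1.37), AT5G03350 (4.62), AT5G62280 (3.62), AT2G03310 (7.36) and AT1G07050 (11.7) lay under the filter's mean signal of 31.8, and with an offset added before the log their changes from trough to peak were 24.6-fold (against 123.0-fold without it), 6.61-fold, 6.20-fold, 4.76-fold, 6.28-fold and 4.70-fold. DFR, with a lowest signal just under that of the filter, changed 14.6-fold with the offset (against 20.2-fold without it). With a single array left out and no offset, the change was 77.0-fold for AT4G14090 (without hour 26), 10.9-fold for AT2G15020 (without hour 34), 8.25-fold for AT5G03350 (without hour 38) and 6.95-fold for AT2G03310 (without hour 46).

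Most rhythms were shallow. The median change from trough to peak was 1.67-fold, with quartiles of 1.48-fold and 2.08-fold, and 683 of the rhythmic probe sets changed at least 2-fold. The median standard error of a fitted peak was 0.74 h. Peaks between hours 20 and 24 were the most frequent, with 503 probe sets or 20.1% of the rhythmic total (95% exact binomial interval 18.5% to 21.7%, which treats probe sets as independent), followed by 480 between hours 8 and 12. The fewest, 272, peaked between hours 0 and 4. Among probe sets with at least a 2-fold change, 178 peaked between hours 20 and 24 and 167 between hours 8 and 12, against 64 between hours 16 and 20.

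**Figure D2:**
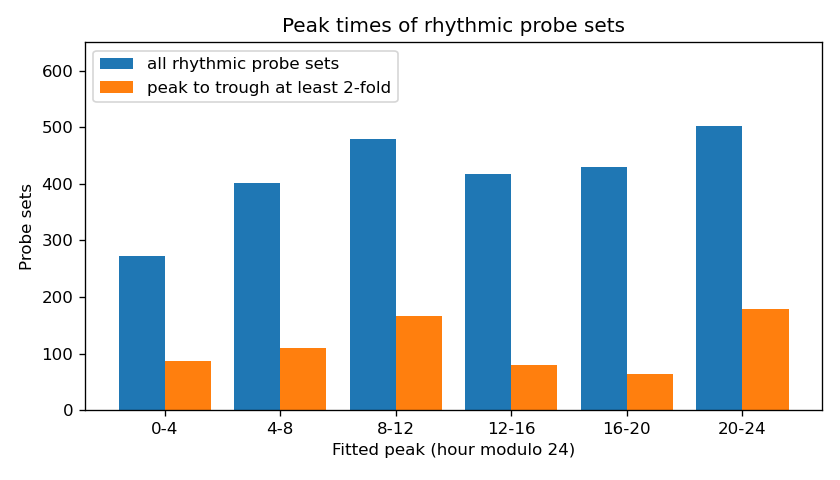
Number of rhythmic probe sets (y axis) by fitted peak time in bins of 4 h (x axis), for all rhythmic probe sets and for those with at least a 2-fold change from trough to peak. The bins at hours 20 to 24 (503) and 8 to 12 (480) hold the most.

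Of the clock genes fixed as a list, 4 had a named and tested probe set. GI, a clock-associated protein that also acts in the timing of flowering, peaked at hour 9.02 with a 6.90-fold change (amplitude 1.39 ± 0.19 SE, adjusted p = 3.02e-04). XCT peaked at hour 21.3 with a 1.57-fold change (adjusted p = 0.025). RVE6 (AT5G52660), a relative of the morning-phased clock transcription factors, had an amplitude of 0.06 ± 0.07 (SE), and TIC one of 0.26 ± 0.10 (SE), and neither was called (adjusted p of 0.80 and 0.19). So 2 of 4 were rhythmic, and 2 adjusted over the list alone, against 16.8% of all 7252 tested loci. The difference in share did not pass (Fisher's exact test, two-sided, adjusted p = 0.21). With 4 genes, this does not show that the shares are alike. The call for XCT was lost without hour 26, 46, 54 or 70, each left out alone, and in fits at 22 h and 26 h, with an adjusted p of up to 0.076.

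All 3 tested members of the cold response list were rhythmic, and 3 adjusted over the list alone. COR15A and COR15B, which encode chloroplast proteins that protect membranes in the cold, changed 6.93-fold and 8.92-fold with peaks at hours 9.55 and 10.9, and the dehydrin COR47 changed 1.95-fold with a peak at hour 11.8. Their mean peak was hour 10.8. The list exceeded the other tested genes, of which 16.8% were rhythmic over all 7252 loci, in its share of calls (Fisher's exact test, adjusted p = 0.038), and its mean profile was rhythmic (permutation test, adjusted p = 3.20e-04). Fisher's test treats members as independent, but COR15A (AT2G42540) and COR15B (AT2G42530) have neighbouring locus numbers. Signal of either transcript on the probe set of the other was not tested.

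Both tested genes of starch breakdown were rhythmic, and 2 adjusted over the list alone. DPE1, which processes maltotriose in the chloroplast, changed 3.81-fold with a peak at hour 11.1, and PWD (AT5G26570), the phosphoglucan water dikinase, changed 2.63-fold with a peak at hour 13.2. DFR was the only tested member of the flavonoid list, and LYC, the lycopene cyclase, the only one of the carotenoid list (1.35-fold, peak at hour 22.4, adjusted p = 0.041), and each list had 1 call adjusted over the list alone. The call for LYC was lost in 12 of 26 alternatives, 8 of which left out a single array, those at hours 34, 38, 42, 46, 50, 58, 62 and 70.

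Genes of photosynthesis were divided. LHCB4.2 and LHCB4.3, antenna proteins of photosystem II, were rhythmic with peaks at hours 3.47 (2.71-fold) and 20.6 (2.29-fold), while LHCB4.1 had an amplitude of 0.18 ± 0.07 (SE) and was not called (adjusted p = 0.20). Thus 2 of 3 antenna genes were rhythmic, and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 0.15). The mean profile of the antenna list did not pass (permutation test, adjusted p = 0.059). It passed with quantile normalization, without hour 26, without hour 74 and without both, with adjusted p of 0.0022 to 0.24 over 17 alternatives. In the Calvin cycle, SBPASE changed 1.69-fold with a peak at hour 19.1, and RCA and PRK were not called (adjusted p of 0.33 and 0.57), which left 1 of 3, and 1 adjusted over the list alone (Fisher's exact test, adjusted p = 0.48). In chlorophyll synthesis, 3 of 4 genes were rhythmic, and 3 adjusted over the list alone. They were PORB (2.17-fold, peak at hour 9.36), HEMB1 (1.37-fold, hour 10.9) and CHLM (1.32-fold, hour 3.46), and GSA1 was not called (adjusted p = 0.28). The share in that list exceeded the other genes (Fisher's exact test, adjusted p = 0.044), but its mean profile was not rhythmic (permutation test, adjusted p = 0.15). The calls for PORB, HEMB1 and CHLM were lost in 8, 3 and 6 of 26 alternatives, among them the removal of hour 34, 46, 54 or 58 for PORB, 26 or 58 for HEMB1, and 42, 50, 54 or 62 for CHLM. Without any 1 of these 8 arrays, at a 26 h period or without linear time the share in the chlorophyll list no longer passed Fisher's test (adjusted p of up to 1), while that in the antenna list passed without hour 26 (adjusted p = 0.013).

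Among light signalling and growth genes, HYH, a transcription factor that acts in light responses, changed 4.70-fold with a peak at hour 21.4 (2.95-fold with an offset; lowest signal 14.9). The expansin EXPA8, a protein that loosens cell walls, changed 2.58-fold with a peak at hour 6.20, and the gibberellin receptor GID1A changed 1.55-fold with a peak at hour 11.2. Its relative GID1B was not called (amplitude 0.06 ± 0.06 SE, adjusted p = 0.76). With 3 of 4 rhythmic, and 3 adjusted over the list alone, the share exceeded the other genes (Fisher's exact test, adjusted p = 0.044), while the mean profile, which averages members with different peaks, was not rhythmic (permutation test, adjusted p = 0.37). The same 3 of 4 were called without hour 34 or 62, each left out alone, and without linear time, but the share no longer passed (adjusted p of up to 0.065).

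**Figure D3:**
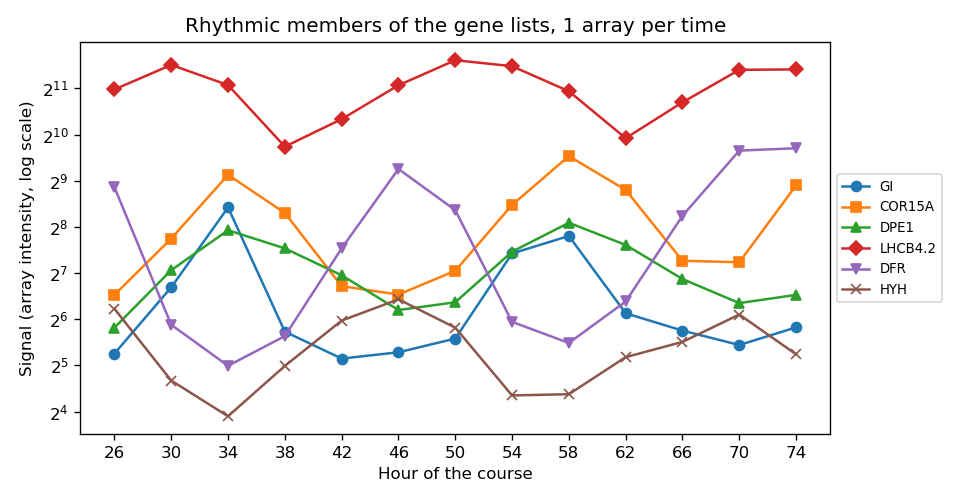
Signal on a log axis (y axis) against the hour of the course (x axis) for 6 rhythmic genes, 1 array per point. GI, COR15A and DPE1 peak between hours 9 and 12 of each day, HYH and DFR between hours 21 and 23, and LHCB4.2 at hour 3.47.

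Reference genes changed little. SAND and TUB6 were called rhythmic with changes of 1.33-fold and 1.32-fold, and the other 4 of 6, TIP41 and AT5G15710 among them, were not called (2 were called adjusted over the list alone, Fisher's exact test, adjusted p = 0.36). The mean profile of the list was rhythmic (permutation test, adjusted p = 0.045), but not at 26 h or without any 1 of the arrays at hours 26, 34, 42, 46, 50, 54, 58 and 70 (adjusted p of up to 0.24). The call for SAND was lost in 14 and that for TUB6 in 16 of 26 alternatives, 9 of them for SAND and 11 for TUB6 by leaving out a single array, at each hour from 26 to 58 except 54 for TUB6, which also lost it without 62, 66 or 70, and from 26 to 58 for SAND. The root markers EXPA7, EXPA18 and PYK10 gave 0 calls of 3, and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 1). ICL, an enzyme of early seedling lipid use, was not called over all probe sets (adjusted p = 0.13), and as the only tested member of its list it gave 1 call adjusted over the list alone.

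The second comparison asked which transcripts drifted over the 48 h apart from the daily cycle. Among probe sets with a single named gene, which were 20 of the 49 rising and 36 of the 82 falling calls, the steepest rise was that of AT4G01390, by 1.95 ± 0.32 (SE, log2 per 24 h), followed by AT1G66100 (1.31), AT4G17470 (1.25), COR15A (0.88) and BGLU33 (0.84), a member of the beta-glucosidase family. The steepest fall was that of AT4G39675, at -1.81 per 24 h, followed by AT3G01190 (-1.06), AT5G64100 (-1.02), AT5G66390 (-0.995), listed as peroxidase 72, and AT5G54370 (-0.97). EXPA8 also fell, at -0.47 per 24 h (adjusted p = 0.0067). The lowest signals of AT4G01390 (11.1), AT4G17470 (7.74), AT4G39675 (8.86), BGLU33 (25.7) and AT5G54370 (23.9) lay under the filter's mean signal of 31.8. With an offset added before the log the slopes per 24 h were 1.42 for AT4G01390, 0.91 for AT4G17470, -1.25 for AT4G39675 and 0.64 for BGLU33. The slope of AT5G54370 was also shallower with the offset, and all of these transcripts were still called. In limma's moderated test, 131 probe sets drifted (1.0%), of which 49 rose and 82 fell, and 40 of the 131 were also rhythmic. The count was 49 without hour 26, 80 without hour 42, 75 without hour 74 and 21 without hours 26 and 74 together, and only 8 in a fit without moderation. The arrays of hours 26 and 74 had the largest residual SDs, 0.26 and 0.28 (log2), against 0.18 to 0.24 for the others, and 17 of the 131 calls were shared with the fit that left out both. Of the 11 transcripts named here, 10 were not called without moderation, 7 without hours 26 and 74 (AT5G54370 at -0.58), 5 without 24 h terms (COR15A at 0.44, adjusted p = 0.85), 3 with 26 h terms, and 3 without hour 26 alone, where AT4G01390 had a slope of 1.67, AT3G01190 of -0.86 and AT5G54370 of -0.83.

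**Figure D4:**
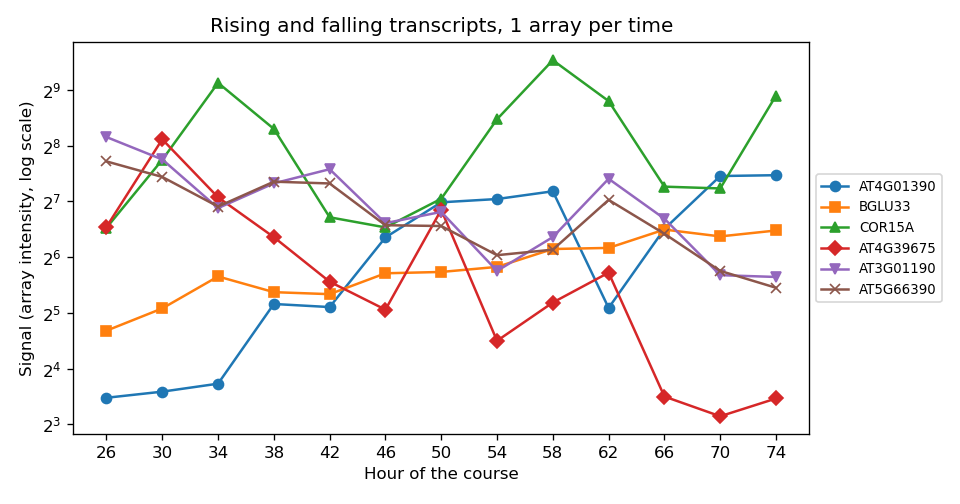
Signal on a log axis (y axis) against the hour of the course (x axis) for 3 rising and 3 falling transcripts, 1 array per point. BGLU33 climbs from 25.7 at hour 26 to 89.2 at hour 74, and AT5G66390 descends from 210.5 to 43.8.

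Of the 8 gene lists with at least 3 tested members, 1 passed the permutation test of drift. The light signalling and growth list had a mean slope of -0.23 ± 0.09 (SE over members, log2 per 24 h). It passed as falling (permutation test, adjusted p = 0.0057), with EXPA8 its only member called, and 1 adjusted over the list alone. The random orders of that test also break the 24 h terms, and 3 of the list's 4 members were rhythmic, so this p may be too small. Exchanges that keep the time of day were not run for lists. The slopes of HYH (-0.26), GID1A (-0.07) and GID1B (-0.11) were not called. In camera the list passed with the preset correlation of 0.01 (adjusted p = 0.0053), and no list passed with an estimated correlation, where this one had an adjusted p = 0.058. No list passed the permutation test without hour 74. In the cold list, 1 of 3 rose, and 2 adjusted over the list alone, with a permutation adjusted p = 0.37. The starch and flavonoid lists, with 2 and 1 tested members, gave 0 drift calls, and 1 each adjusted over the list alone. The root markers had slopes of -0.20 ± 0.17 (EXPA7), -0.03 ± 0.12 (EXPA18) and 0.05 ± 0.07 (PYK10; SE), with 0 calls and 0 adjusted over the list alone.

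The third comparison set the cycle of hours 50 to 70 against that of hours 26 to 46. No transcript passed limma's test of a difference between the cycles, with 0 calls, 527 probe sets at an unadjusted p under 0.05 (682 would be reached by chance), 0 calls in a fit without moderation and 10 calls in a fit at a 26 h period. The smallest p-values among named genes were those of AT1G80130, AT5G15780, AT4G01390, GSTU26 and AT3G61210, with an adjusted p = 1.00 for each. Over the rhythmic probe sets the median ratio of the later to the earlier amplitude was 0.95, with quartiles of 0.77 and 1.19 and a jackknife standard error of 0.090, so it did not differ from no change by more than its error. Their median shift of the fitted peak, later minus earlier, was -0.65 h, and -0.73 h among those that changed at least 2-fold. No error was computed for that shift. In simulated data with an amplitude of 1 in the earlier cycle, the test recovered 83.6% of rhythms lost in the later cycle and 62.1% of doubled amplitudes. It recovered 5.97% of amplitudes multiplied by 0.5, so a change of that kind was seldom detected, and changes under 2-fold were not simulated. The median amplitude of the rhythmic probe sets was 0.37, and recovery of changes in rhythms of that size was not measured.

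The period that fitted best had a median of 23.5 h over the rhythmic probe sets, with quartiles of 22.5 h and 24.5 h, on a grid of 0.5 h steps. It was 23.5 h with each array left out in turn. Those probe sets were selected by a 24 h fit, which favours periods near 24 h. Over the 2170 probe sets selected by a fit at 22 h the median was 23 h, and over the 1770 selected at 26 h it was 24 h, so the median moved with the selection. GI fitted best at 24 h and XCT at 23.5 h. RVE6 and TIC, which were not rhythmic, had their lowest residuals at 27.5 h.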

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

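The values of dim probe sets given first, their refit with an offset, the exchanges of arrays for drift, and the tests of falling transcripts given last, were chosen after the results were seen. The other tests on reordered and exchanged arrays were set before any reordered count was seen, though after the real counts. Rhythms also appeared among probe sets too dim for the comparisons above. When no filter was applied, 182 of the 9099 dim probe sets were rhythmic, or 2.00%. The p-values were adjusted over all 22746 non-control probe sets, so the share of false calls among the dim ones alone may be higher. Among them were the cold response genes COR27 (amplitude 2.41 ± 0.43 SE, peak at hour 12.9, adjusted p = 0.0055) and COR28 (1.45 ± 0.24, hour 12.3, adjusted p = 0.0034), and IAA29, an auxin response gene (0.99 ± 0.16, hour 6.43, adjusted p = 0.0029). CDF5, a regulator of flowering time, had an amplitude of 0.42 ± 0.11 and was not called (adjusted p = 0.066). The sizes of these swings depend on dim values: the lowest signals of COR27 and COR28 were 1.32 and 5.03, and with an offset added before the log the changes from trough to peak were 7.96-fold for COR27 (against 28.2-fold), 3.57-fold for COR28 (7.49-fold) and 2.53-fold for IAA29 (3.95-fold). All 3 were called with the offset, where 219 dim probe sets were rhythmic.

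Random orders of the arrays bore on the counts of calls. Of 100 orders, 1, the real one, gave as many as 2504 rhythmic probe sets, and the highest other gave 440. A chance order of the arrays was excluded there, to the limit of 100 orders. Random orders also break any likeness of neighbouring arrays, which was not tested apart. For the 131 drifting probe sets 1 of 100 orders gave as many and the highest other gave 1, which does not settle it, because a reordering also breaks the 24 h terms and rhythms then widen the residuals. Exchanges of arrays that share a time of day keep those terms. Of 96, 1, the real one, gave as many, and the highest other, which moved 2 arrays, gave 54. The real order thus gave more calls than any other exchange, to the limit of 96 exchanges. With 1 array per time, the test cannot tell a drift from chance deviations of the arrays at hours 26 and 74. Of the 131 calls, 17 were shared with the fit without both, so chance in those arrays stays open. For the cycles, 8 of the 32 exchanges of arrays 24 h apart gave as many as the 527 probe sets at an unadjusted p under 0.05, and the highest other gave 640, so chance was not excluded there.

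The 82 falling probe sets had a median slope of -0.57 (log2 per 24 h). A falling share of root tissue would lower root transcripts alike. The 3 root markers EXPA7, EXPA18 and PYK10 had a mean slope of -0.062 ± 0.075 (SE). The lower bound of 2 standard errors, -0.21, lay above -0.28, which is 0.5 times that median. An error taken over 3 markers is poorly known, and they differed: EXPA7 had a slope of -0.20 ± 0.17 and PYK10 of 0.05 ± 0.07 (SE). These values therefore do not settle whether the share of root tissue fell. Dependence on the arrays at the ends of the course stays open: the median slope was -0.52 without hour 26 and -0.58 without hour 74, but these probe sets were picked on all arrays, and the drift calls fell to 49 and 75. Falling RNA integrity stays open too, because the mean ratio of 3 prime to 5 prime control signals had a slope of 0.13 ± 0.09 (SE, permutation p = 0.19) with an interval reaching 0.32. A change in particular root cells, or with the age of the seedlings, was not tested.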

How the results depend on the processing

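The removal of hours 26 and 74 together, the selection of probe sets at 22 h and 26 h, and the offset with no filter, were chosen after the data were seen. Across scalings, offset, filters, variance models, shapes and periods the rhythmic count stayed between 1770 (period of 26 h) and 2567 (quantile normalization), and 2047 to 2441 with each array left out in turn. Of the 2504 calls, 1661 (time of day as a factor) to 2499 (offset) were shared with an alternative. The median period was 23.5 h with quantile normalization, without a filter, without linear time and with arrays left out. It was 23 h and 24 h over probe sets selected at 22 h and 26 h, which favours periods near those, and was not computed under other settings. The amplitude ratio ranged from 0.92 to 0.99 with each array left out. Rhythmic list members numbered 15 to 20 with an array left out and 14 at 26 h, against 20. The share of peaks between hours 20 and 24 was 18.6% (26 h), 20.1% (quantile normalization) and 20.3% (no linear time).

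The drift count moved widely. Against 131, it was 8 without moderation, 56 without 24 h terms, 46 with 26 h terms, 21 without hours 26 and 74, and 49 to 169 with an array left out. Without moderation the slopes are the same and each variance is estimated from its own probe set alone. For the other changes the cause was not tested. The cycle comparison gave 10 calls with a period of 26 h and 0 otherwise, including each array left out, and the cause was not tested. Of 17 alternatives, Fisher's test of a list's share changed sides in 10 for chlorophyll synthesis, 3 for light signalling, 2 for the antenna and 0 for the other 5 lists, and the test of the mean profile in 10 for the reference genes, 4 for the antenna and 1 each for chlorophyll synthesis and the Calvin cycle. The lists that passed the permutation test of drift numbered 0 to 1 with an array left out, against 1. Of the checks of single genes, 783 amplitudes and 232 slopes stayed called, and 91 and 28 did not. Among the slopes 0 reversed, whereas an amplitude is never negative and so cannot reverse. Signal over background limits dim genes. No paired analysis was possible because the labels give every array the same replicate number, which pairs none of them. Arrays 24 h apart share a time of day, and with time of day as a factor 145 probe sets drifted.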

Other observations

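The gene groups of this part were formed after the data were seen, whereas the test of adjacent genes was set before its result was. The peaks of 2 further genes of anthocyanin synthesis are given as values with no test of the pathway. UF3GT, a flavonoid glycosyltransferase, changed 12.8-fold with a peak at hour 22.0, and AT5MAT, an anthocyanin malonyltransferase, changed 10.3-fold with a peak at hour 21.9 (4.96-fold with an offset; lowest signal 3.85). Genes encoded in the plastid were seldom called rhythmic: 1 of 69, psbJ, was called, a smaller share than among the other genes (Fisher's exact test, adjusted over 30 gene groups, p = 0.0020). Fisher's test treats genes as independent, and whether the probe sets of these genes are noisier than others was not tested. Of the 23 genes with a symbol that begins with UGT, a name for glycosyltransferases, 11 were rhythmic (Fisher's exact test, adjusted p = 0.0081). The peaks of these 11 were scattered, with a resultant length of 0.21. Glycosyltransferases under other symbols, AT4G14090 and UF3GT among them, were not in that group. The mean profile of neither group was rhythmic (permutation test, adjusted p of 0.75 and 0.27), while 12 of the 30 groups passed that test and 2, these, passed Fisher's.

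Rhythmic genes that lie side by side on a chromosome peaked together more often than chance gives. Of 70 adjacent pairs, 45.7% had peaks within 3 h, against a mean of 25.9% in 10000 random reassignments of the peaks (permutation p = 3.00e-04). Pairs 2, 3, 4 and 5 genes apart had shares of 30.2%, 28.0%, 29.8% and 24.3%, against mean random shares of 25.9%, 25.8%, 25.9% and 26.1%, and none passed the test (permutation p of 0.31, 0.41, 0.32 and 0.66). A shared peak of adjacent genes may reflect shared regulation, as a hypothesis. Signal of one transcript on the probe set of a similar neighbour cannot be told apart from it here, because leaving out probe sets marked as shared removed none of the 70 pairs and left the p at 3.00e-04, and no sequences were compared.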
